A study of Mus musculus with 400 samples.

How the data were processed

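Single cells that carried the red fluorescent protein tdTomato were sorted by flow cytometry from dissociated cervical dorsal root ganglia (DRG) of 6 naive mice, in which a Cre recombinase driven by the Nav1.8 gene Scn10a switches the reporter on. Each sorted cell was sequenced as its own library, in 4 runs. The labels list 400 cells, and 394 of them have a column in the tables; the other 6 were not analysed here. The labels name the mice Blue and Red in run 1, Control in run 2, Control1 and Control2 in run 3 and Control6 in run 4, and each mouse was treated as 1 replicate. All mice were of 1 condition, so every comparison was made between classes of cells within the same mice.

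The submitters' processing notes name STAR 2.7.3a and the mouse build mm10. The deposited values are a signal per gene and cell: the count of the gene in the cell times a factor of that cell, which is not given in the sources used here. Low values were whole multiples of the value of 1 count within a tolerance of 0.1, for a median of 96.4% of them, and whole reads could be recovered in 250 columns and were not claimed in the other 144. Counts below are therefore recovered counts. They gave the depth of cells and entered the alternatives with thinned cells, at least 10 counts, edgeR or DESeq2, and the simulation. Columns in which whole reads were not claimed entered these alternatives and the simulation too, rounded to whole counts. Values that are fractions of a count occur where genes share reads. They made up over 20% of the low values for 1176 genes, and any such gene named below is marked as uncertain. No column was left unused. The tables hold 24781 gene entries; 26 of them carried dates in place of gene symbols and were left out with 0.154% of the signal. The ribosomal RNA gene Rn45s, on average 7.11% of the signal of a cell, was left out of the totals, and values were then scaled per cell to CPM (counts divided by the total of the cell, on the usual scale). Gene positions were taken from GENCODE vM21 on GRCm38 (mm10), in which 97.8% of the symbols were found.

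Cells with at least 500 detected genes were kept (371 of 394). The 23 cells left out held at most 431 counts. No column was identical to another. Cells were clustered with the Leiden method (scanpy 1.11.5, igraph 0.11.9, resolution 1, 20 principal components, 15 neighbours) on 88 marker genes, which were taken from 105 marker genes in 18 lists fixed before the data were examined. A cluster took the name of the neuron class with the highest marker score. It was left unnamed where its 10 strongest genes held more glial genes than markers of that class, or where counts were low and no such marker stood among the 10. Rules for the unnamed clusters were set after the data were seen. Because the classes were defined on genes measured in the same cells, p-values of class comparisons are conditional on the classes. Marker genes were left out of every gene test.

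For each comparison the mean CPM per mouse and class was formed from classes with at least 3 cells in the mouse. The fixed design foresaw edgeR with TMM on summed counts. Since the deposited unit is not counts, the test was changed after the files were examined to limma 3.58.1 (R 4.3.3) on log2(CPM + 5), with mouse as a block and a trended prior, on genes with a mean of at least 10 CPM. The pseudocount makes differences of weakly expressed genes smaller than the ratio of their CPM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For 431 genes in 18 readout lists, likewise fixed before the data were examined (427 in the tables), members past this threshold were counted, also with adjustment over the list alone. Each list with at least 3 tested members was tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Genes were named by a fixed rule. It took the 6 largest differences each way among genes past the threshold, with a mean of at least 20 CPM and the same direction in every mouse, up to 3 members of smallest p per readout list, and 10 genes of nociceptor biology given in advance. Predicted genes, pseudogenes and mitochondrial, ribosomal and haemoglobin genes were not named among the largest. Some genes that meet this rule are not reported here, and they were left out of the search for outlying mice.

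Scn10a was compared between classes by exact two-sided sign flips over mice, and class shares by permutation of mouse labels over cells (100000 shuffles, so that 1e-05 is the smallest p) and by Fisher's exact test in run 1. Intervals for shares of cells are exact Clopper-Pearson 95% intervals and cover counting error only. In a simulation, sums of counts per mouse and class were drawn from the totals and spread of the recovered counts, with 200 genes changed. Of tested genes changed 2-fold, limma recovered 28.3% for NP-like against PEP-like, 22.7% for TH-like and 34.4% for NP1-like neurons. For genes changed 4-fold the shares were 85.3%, 66.7% and 86.5%. False calls numbered 1, 0 and 0. No single cells were simulated, and the main test averaged CPM over cells, so these rates need not hold for it.

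Alternatives fixed before the data were examined left out the mouse block or each mouse in turn, or used DESeq2 1.42.0 or edgeR 4.0.16 with DESeq2 size factors on recovered counts, a mean over cells of log2(CPM + 1), no filter on low values, at least 10 counts in every sum, at least 5 cells, cells with at least 2000 genes, or cells thinned to 12168 counts (37 cells were too shallow). Others clustered on 2000 variable genes or at resolution 0.5 or 2, took the class of the highest marker score, or used the mice of run 1 or of runs 2 to 4. Alternatives added after the data were seen were pseudocounts of 1 and 20, Rn45s in the totals and median-of-ratios scaling. So were the 2 clusters left unnamed for their glial genes joined to their nearest class, and PEP1-like cells as the only PEP-like cells. EdgeR with TMM, the test first foreseen, was run as an alternative on recovered counts, which was also set after the data were seen. A comparison of NF-like (large-diameter) neurons had been fixed as well and could not be made, since no cluster took that name. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.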

Results

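The data describe the transcriptomes of single DRG cells from naive mice whose Scn10a-expressing lineage was marked with tdTomato. After removal of nearly empty libraries, 371 cells remained, 254 from the 2 mice of run 1 (Blue and Red), 50 from Control, 19 from Control1, 23 from Control2 and 25 from Control6. Kept cells held a median of 32932 recovered counts (range 1094 to 348210) and 6581 genes. The median per mouse was 29883 counts in Blue, 33429 in Red, 47994 in Control, 28716 in Control1, 26814 in Control2 and 33211 in Control6. Genes of general neuronal identity, such as Snap25 and Uchl1, summed to 9306 CPM per cell. Marker sums were 4.56 CPM for macrophages, 1.39 for lymphocytes, 0.642 for neutrophils, 1.43 for endothelium and 32.7 for fibroblasts. They were 21.7 CPM for erythroid cells and 144 for mural cells. Satellite glial and Schwann cell markers were more abundant, at 917 and 664 CPM.

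The composition of the marked population was asked first. Clustering gave 9 clusters, and 308 cells fell into 6 named neuron classes. The NP1-like class (86 cells), named after the non-peptidergic neurons that express the receptor gene Mrgprd, was led by Mrgprd, Lpar3 and Prkcq. NP2-like cells (48) were led by Mrgpra3, an itch receptor gene, and NP3-like cells (47) by the peptide genes Sst, Nppb and Nts. PEP1-like cells (57), peptidergic neurons, had Adcyap1 and Gal at the top and Tac1 among the 10 strongest genes, and held 9961 CPM of Calca (SD 2455, n = 4 mice), which encodes CGRP. Their class score of 2.215 was close to their erythroid score of 2.204, which came from few cells (median erythroid sum 0), and Ttn, a muscle gene among the 10, had a count in 1 of 57 cells. PEP2-like cells (23) had Trappc3l and the Schwann cell marker S100b at the top, with the class marker Fam19a1 and Thy1 among the 10 strongest genes. The class marker Smr2 had a count in 0 of these 23 cells, so the name rests on few markers. They held 4139 CPM of Calca (SD 1762, n = 2 mice) and 1423 CPM of Nefh (SD 254). TH-like cells (47), named after tyrosine hydroxylase and known as low-threshold touch neurons, were led by Th, P2ry1 and Cckar. No cluster was led by markers of NF or of Trpm8-type cold neurons, whose markers summed to 440 and 15.1 CPM over all kept cells, so the comparison of NF-like neurons with other neurons has no value.

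Averaged over the 6 mice, NP1-like cells made up 26.3% of kept cells (SD 7.90), NP2-like cells 9.72% (SD 6.12), NP3-like cells 12.6% (SD 5.34), PEP1-like cells 12.1% (SD 8.73), PEP2-like cells 8.84% (SD 11.4) and TH-like cells 11.3% (SD 2.66). Unnamed cells made up 19.2% (SD 13.4). The mean share of PEP2-like cells rested on mouse Control and was 4.61% without it. At resolution 0.5 that share was 0 and the mean share of PEP1-like cells was 29.5%. Mice differed in composition by more than counting error (permutation p = 1e-05 over 371 cells, the smallest p possible). PEP2-like cells were 30% of the cells of mouse Control against 0 to 12% in the other mice, while PEP1-like cells were 2% there, 0 in Control2 and 15.8% to 19.5% in the other 4 mice. Between Blue and Red, both of run 1, no difference in composition was detectable (permutation p = 0.856). NP1-like cells were 23.02% and 20.3% of their cells and TH-like cells 14.3% and 14.1%, and Fisher's exact test gave an adjusted p of 1 for every class. The 2 mice of run 3 gave a permutation p of 0.0584 with 42 cells. Mouse and run cannot be told apart beyond these 2 runs.

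**Figure D1:**
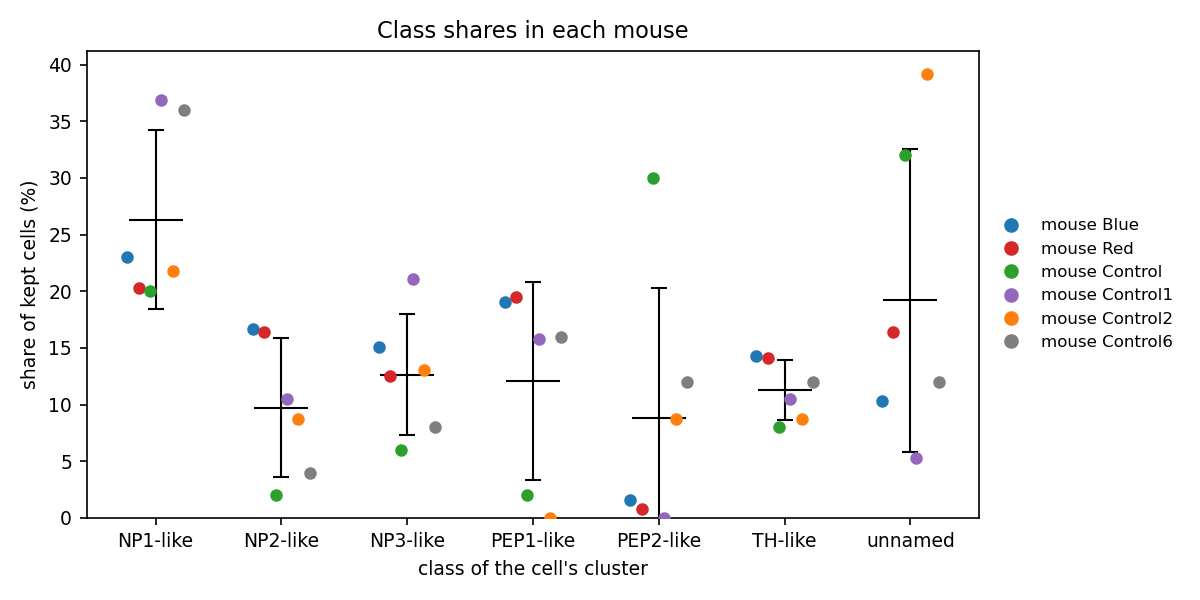
Share of kept cells in each class (y axis, percent) for the 6 mice (points, coloured by mouse), with the mean over mice and its SD (bars). Blue and Red lie close together, and mouse Control has the highest PEP2-like share, 30%.

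Of the 63 unnamed cells, 54 lay in 2 clusters whose 10 strongest genes held more glial genes than markers of the nearest class (1 against 0 in the larger, 3 against 1 in the smaller). The larger (34 cells) carried 9688 CPM of Calca and 3532 of Tac1, close to PEP1-like cells at 11164 and 4278, together with 2399 CPM of Apoe, a satellite glial marker, against 129 in PEP1-like cells. Among its leading genes were Calb1 and Smr2, which were markers of other neuron classes in the fixed lists. The smaller (20 cells) carried 673 CPM of Mrgprd, against 705 in NP1-like cells, with Gpnmb and Cdh19 among its leading genes. The last 9 unnamed cells, all from mouse Control, had a median of 2328 counts.

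Scn10a itself, whose promoter drove the label, had a count in 98.1% of kept cells (364 of 371, 95% interval 96.2% to 99.2%). The gene lies on chromosome 9 from 119608456 to 119719322. In the 23 libraries left out for low content it had 0 counts, but these held at most 431 counts each, too few to tell whether it was expressed. By class, the mean over mice was highest in NP1-like cells at 980 CPM (SD 82.7, n = 6 mice) and lowest in TH-like cells at 242 CPM (SD 5.03, n = 4 mice), where 43 of 47 cells (91.5%) had a count. NP2-like cells held 850 CPM (SD 39.2, n = 2), NP3-like cells 577 (SD 43.2, n = 5), PEP1-like cells 507 (SD 118.3, n = 4) and PEP2-like cells 484 (SD 88.8, n = 2). NP-like cells exceeded PEP-like cells by 0.78 on the log2 scale (SD 0.25) in 5 of 5 mice (exact p = 0.0625, the smallest possible with 5 mice, adjusted over the 3 comparisons 0.0938). TH-like cells were lower than other neurons in 4 of 4 mice, by −1.54 (SD 0.05, exact p = 0.125, the smallest possible, adjusted 0.125). NP1-like cells exceeded NP2-like and NP3-like cells by 0.50 (SD 0.28) in 6 of 6 mice (exact p = 0.0313, the smallest possible, adjusted 0.0938), and by 0.38 with cells thinned to equal depth, where the exact p was 0.0625.

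**Figure D2:**
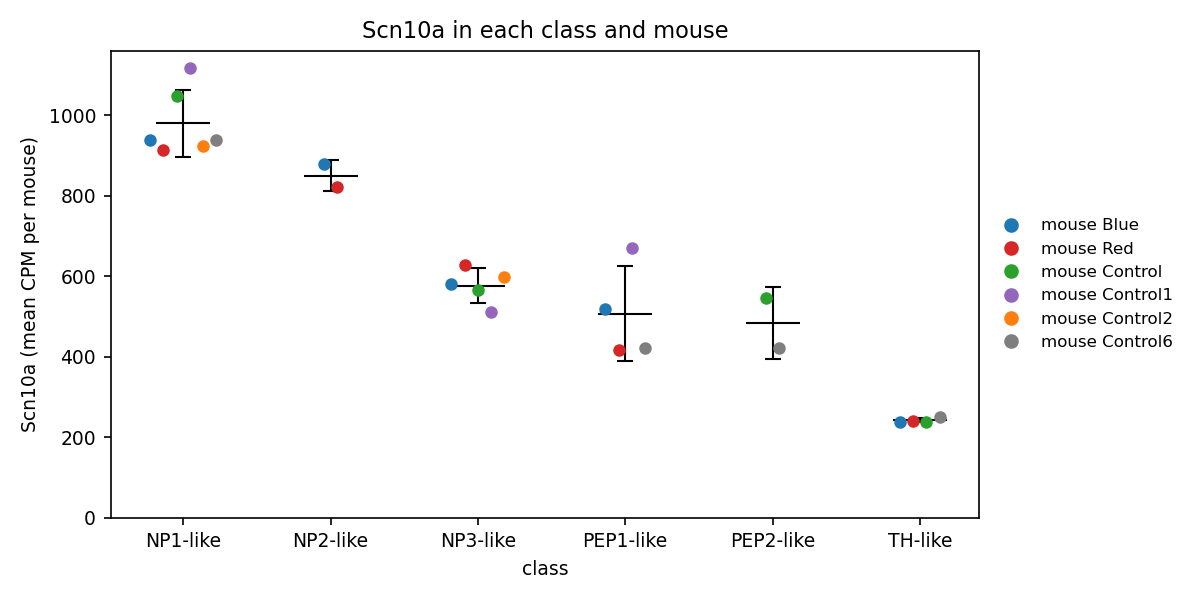
Mean Scn10a level (y axis, CPM) in each class for each mouse with at least 3 cells of the class (points), with the mean over mice and its SD (bars). The 4 TH-like values lie between 239.0 and 249.5 CPM, below every other class.

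NP-like neurons (NP1, NP2 and NP3 together) were compared with PEP-like neurons (PEP1 and PEP2 together) in 5 mice. The question was what separates them beyond the markers that define them. The NP-like side was not free of peptide genes: NP2-like cells held 5018 CPM of Calca (SD 17.2, n = 2 mice), in 48 of 48 cells. PEP2-like cells held 4139 CPM. The largest genes on the NP-like side were Grik1, a kainate-type glutamate receptor subunit, at 805 CPM (SD 183) against 34.1 (SD 69.6), a log2 difference of 5.88 (SE 0.60, adjusted p = 0.00015), and Synpr, a synaptic vesicle protein gene, with a difference of 4.84 (SE 0.61). Tmem45b (4.66), Ppp1r1a (4.65), Ctxn3 (4.49) and Kcnip2 (4.12), which encodes an auxiliary protein of A-type potassium channels, came next. On the PEP-like side, Adcyap1, which encodes the neuropeptide PACAP, stood at 994 CPM (SD 663) against 15.7 (SD 25.3), a log2 difference of −5.84 (SE 0.50, adjusted p = 5.44e-05). Fxyd7 (−5.27), a regulator of the sodium pump, the protein kinase C gene Prkcb (−5.21), Pcp4 (−4.50; exons shared with Igsf5), Cyp1b1 (−4.28) and the galanin gene Gal (−4.22) followed. All 12 moved the same way in 5 of 5 mice, which the rule that named them required. Not every class on a side shared a difference: Grik1 stood at 1406 CPM in NP1-like cells but at 74.8 in NP2-like and 1.04 in NP3-like cells, against 3.18 in PEP1-like and 84.2 in PEP2-like cells, and Kcnip2 at 278, 53.9 and 15.8 against 2.04 and 20.03. Gal and most Adcyap1 were in PEP1-like cells (221 and 1387 CPM), with 7.18 and 84.4 in PEP2-like cells. Grik1 lies on chromosome 16 from 87895900 to 88290265 and Adcyap1 on chromosome 17 from 93199017 to 93206537.

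Among ion channels, 2 of 11 tested voltage-gated sodium channel genes were higher in NP-like cells, Scn11a by 1.41 (SE 0.10) and Scn10a by 0.78 (SE 0.12), and Scn3a was lower by −1.96 (SE 0.48), with 8 not past the threshold. Scn9a differed by 0.31 (SE 0.10, adjusted p = 0.0812). Of 18 TRP, Piezo, ASIC and P2X channel genes, 5 were higher, with Trpc6 at 3.19, P2rx3 at 2.71 and Piezo2 at 0.96 (856 CPM in NP1-like but also 862 in PEP2-like cells), and Asic3, an acid-sensing channel gene, was lower by −4.20 (SE 0.33). The remaining 12 did not pass, among them the capsaicin receptor gene Trpv1 (−1.51, SE 0.47, adjusted p = 0.0608) and Trpa1 (0.79, SE 0.28, adjusted p = 0.102). Potassium and HCN channel genes went both ways, 10 higher and 11 lower of 41, with Kcnip4 at 3.02 and Kcnc1 at −3.19. Of 12 calcium channel genes only Cacna1e passed (−2.38). Adjusted over the list alone, 5 sodium, 9 TRP, Piezo, ASIC and P2X, 28 potassium and HCN and 1 calcium channel genes passed.

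Among receptors and peptides, single genes also differed between the classes. The low-affinity neurotrophin receptor gene Ngfr was lower in NP-like cells by −3.61 (SE 0.41), as was the artemin co-receptor gene Gfra3 (−3.15, SE 0.39; 181 CPM in PEP1-like but 2.81 in PEP2-like cells), and the GDNF-family receptor gene Ret was higher by 1.15 (SE 0.25). Of 9 neurotrophic receptors, 2 were higher, 3 lower and 4 not past. Itch and inflammatory mediator receptors split into 6 higher, such as Agtr1a (3.70) and Cysltr2 (3.13), and 5 lower, such as S1pr3 (−3.35), of 17. Agtr1a was carried by NP1-like cells (143 CPM, against 14.8 in NP2-like and 0.484 in NP3-like cells) and Cysltr2 by NP3-like cells (161 CPM, against 2.94 in NP1-like and 3.20 in NP2-like cells). Of 10 inhibitory receptors, 4 were lower, such as Adra2c (−2.75) and Npy1r (−3.69), and Npy2r was higher by 1.98 (SE 0.32, adjusted p = 0.00208), although its difference was −0.75 (adjusted p = 0.524) when cells were averaged on the log scale. NP3-like cells alone carried the Npy2r difference, at 673 CPM, while NP1-like and NP2-like cells, at 0 and 0.80, lay below PEP1-like (34.2) and PEP2-like cells (72.7). Neuropeptide genes were lower in 6 and higher in 3 of 16, the latter including Scg3 (2.57) and Cpe (1.39), which encode proteins of secretory granules. Cytokine receptors gave 1 higher, Lifr (1.11), and 2 lower of 17, Tgfbr1 (−2.15) and Il11ra1, for which 21.8% of low values were fractions and the difference is uncertain. In the list of growth factors and cytokines, Cd47, which encodes a membrane protein and not a secreted one, was higher (1.44) and 3 of 14 were lower, such as Kitl (−2.92) and Fgf1 (−1.59), and of 2 innate receptors Nod1 was lower (−2.20). With p adjusted over the list alone, 7 neurotrophic, 12 itch, 8 inhibitory and 3 cytokine receptor genes, 10 neuropeptide genes, 4 of the growth factor list and 1 innate receptor passed.

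In the other lists, Grik1 and 1 more of 11 glutamate and GABA receptor genes were higher, and 2 were lower, such as Grin3a (−2.52), while edgeR on recovered counts gave 1 higher and 5 lower. Btg2 (−2.15), Egr1 (−1.84) and Jun (−1.22) were lower among 17 immediate early and heat shock genes, and Gap43 (−2.62) and Stmn4 (−2.61) among 6 axon injury genes. Transcription factors gave 3 higher, among them Casz1 (2.55), Etv1 (1.92, with 0.656 CPM in NP1-like cells) and Runx1 (1.13), and 2 lower, among them Zeb2 (−4.11), of 15. Runx1 stood at 645 CPM in NP1-like, 81.3 in NP2-like and 305 in NP3-like cells, against 307 in PEP1-like and 55.4 in PEP2-like cells. Only 3 of 80 oxidative phosphorylation genes passed, Ndufv1 (0.51) higher and Atp5h (−0.61) and Cox6c (−0.36) lower, and 4 of 95 ribosomal protein genes, with Rpl28 (0.54) and Rps9 (0.50) higher and Rpl22l1 lower but uncertain, since 58.97% of its low values were fractions. Of 9 other glial genes, Mal (1.92) and Pmp22 (0.89) were higher and Vim (−1.91) lower. Adjusted over the list alone, 8 glutamate and GABA receptor, 5 immediate early, 3 axon injury, 5 transcription factor, 4 glial, 0 oxidative phosphorylation and 0 ribosomal genes passed. Satellite glial markers summed to 164 CPM in NP1-like, 760 in NP2-like, 433 in NP3-like, 336 in PEP1-like and 3296 in PEP2-like cells, whose median depths were 49130, 41160, 18580, 20160 and 80290 counts.

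For NP-like against PEP-like neurons as a whole, 1157 of 9028 genes passed in the limma test, 572 higher and 585 lower in NP-like cells, and 1082 of them moved the same way in every mouse. None of 17 lists tested with camera passed (lowest adjusted p = 0.106), 5 had an unadjusted p under 0.05, 0 passed with an estimated correlation and 4 passed with fry. Sodium channels and itch receptors had a negative median beside an upward test, and the mean was negative for the former only, while glutamate and GABA receptors had a positive mean beside a negative median and a downward test. The median of the itch list turned to 0.32 with edgeR on recovered counts, where 6 of 9 passed, and with thinned cells 12 potassium and HCN channel genes (6 higher and 6 lower) and 5 neuropeptide genes passed. PEP-like cells were mostly PEP1-like in Blue (24 of 26) and mostly PEP2-like in Control (15 of 16), and with PEP1-like cells alone 746 genes passed in 4 mice, 672 of them shared. The count was 767 without mouse Blue, 653 with thinned cells, 738 with no filter on low values, 732 with at least 10 counts per sum, 2013 in the 2 mice of run 1 and 462 in the mice of runs 2 to 4.

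**Figure D3:**
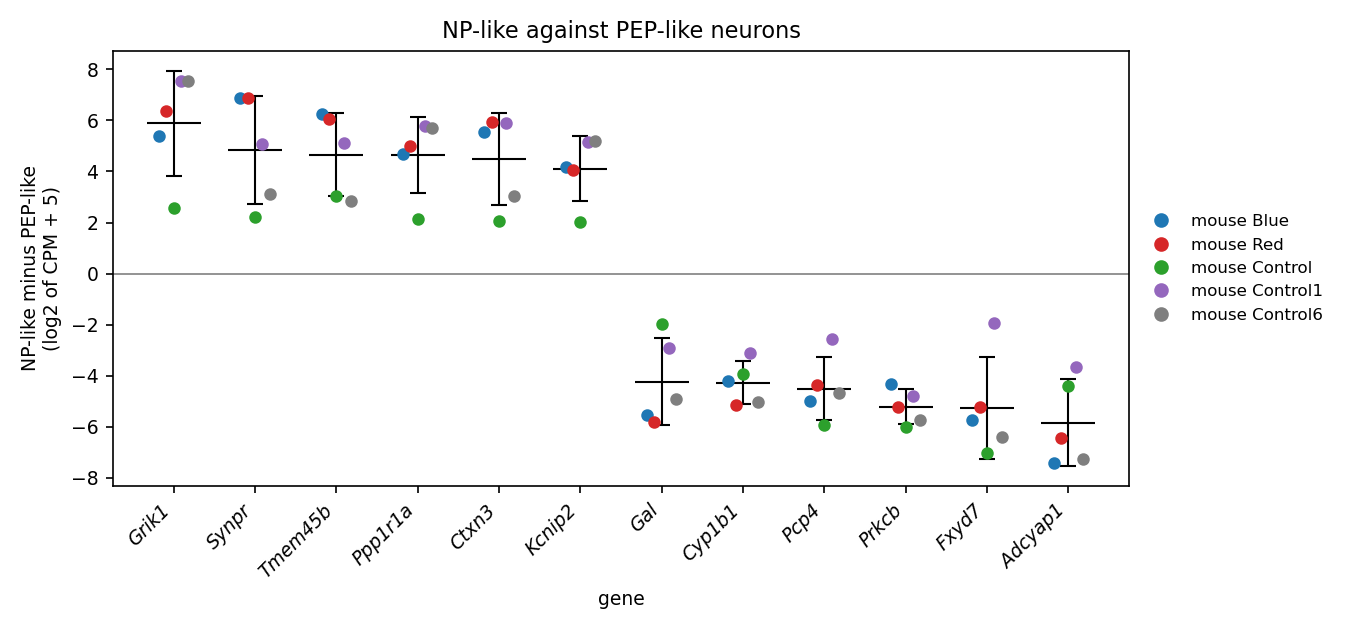
Log2 difference of CPM + 5 between NP-like and PEP-like neurons (y axis) for the 6 largest named genes each way, in 5 mice (points), with the mean and SD (bars). Means run from 5.88 for Grik1 to −5.84 for Adcyap1. Every mouse lies on the same side of 0 for each gene, which the rule that named them required.

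TH-like neurons were compared with all other named neurons in 4 mice, to ask what sets the touch-type class apart among Scn10a-lineage cells. Cckar, the cholecystokinin A receptor gene, stood at 247 CPM (SD 78) against 1.86 (SD 1.24), a log2 difference of 5.17 (SE 0.33, adjusted p = 8.04e-06). The diacylglycerol kinase gene Dgkk (5.08), the ADP receptor gene P2ry1 (4.80), Wfdc2 (4.78), the T-type calcium channel gene Cacna1i (4.61) and the actin-severing protein gene Scin (4.50) were next. The granule protein gene Scg2 was lower, at 7.35 CPM (SD 13.5) against 1080 (SD 112.3), by −6.97 (SE 0.37, adjusted p = 4.68e-06). Also lower were the growth cone gene Gap43 (−5.67), Ptprn (−5.66), Tmem255a (−5.46) and Hs6st2 (−5.40). NP1-like cells, which are among the other neurons, were low in Scg2, Gap43 and Ptprn too (34.5, 10.6 and 0 CPM, means of 6 mice). The transcription factor gene Etv1 was listed at 0 in the TH-like cells of all 4 mice, against 232 CPM (SD 111.8) in other neurons (adjusted p = 1.03e-05), among which NP1-like cells held only 0.656 CPM. Cckar lies on chromosome 5 from 53697776 to 53707705 and Scg2 on chromosome 1 from 79434669 to 79440120.

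The mechanically gated channel gene Piezo2 (chromosome 18, 63010213 to 63387183) was higher in TH-like cells, at 1541 CPM (SD 238) against 467 (SD 215), by 1.82 (SE 0.17), whereas Trpv1 (chromosome 11, 73234292 to 73261242) was nearly absent at 1.09 CPM (SD 2.19) against 157 (SD 95.1), a difference of −4.52 (SE 0.41). P2rx3 (−4.61) and Trpa1 (−1.53) were lower too. Low Trpa1 was not particular to TH-like cells: it stood at 22.3 CPM there, 28.6 in NP3-like and 18.3 in PEP2-like cells, against 134 in NP1-like cells. Of 19 TRP, Piezo, ASIC and P2X genes 3 were higher, 8 lower and 8 not past, and the list moved down (camera adjusted p = 0.0473, adjusted p = 0.279 with an estimated correlation). Camera called sodium channel genes upward as a list, with 6 higher, 2 lower and 4 not past of 12 (adjusted p = 0.0398, adjusted p = 0.317 with an estimated correlation), with Scn3b at 0.89 (SE 0.17) and Scn9a at 0.38 (SE 0.09). The 2 lower members were the nociceptor channels Scn10a at −1.54 (SE 0.10) and Scn11a at −1.58 (SE 0.11). It also called potassium and HCN channel genes upward, with 15 higher, 7 lower and 15 not past of 37 (adjusted p = 0.0398, adjusted p = 0.317 with an estimated correlation), with Kcnd3 at 3.09 (SE 0.18), Kcnj12 at 2.39 and Kcnt1 at −2.11. Without the mouse block neither of these 2 lists passed (adjusted p = 0.0965 for both), and with thinned cells the sodium list gave 1 higher and 2 lower of 11 and the potassium and HCN list 7 higher and 4 lower of 37. Of 13 calcium channel genes 3 were higher, among them Cacna1h (3.26), and 3 lower, among them Cacna1c (−2.96), with a camera adjusted p of 0.995. With p adjusted over the list alone, 11 TRP, Piezo, ASIC and P2X, 11 sodium, 27 potassium and HCN and 11 calcium channel genes passed.

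Itch and inflammatory mediator receptors were lower in 9 of 16 and higher in P2ry1 alone (adjusted p = 0.00379, adjusted p = 0.279 with an estimated correlation), with F2rl2 at −4.07 and Ptgir at −3.77. Neuropeptides and their processing genes were lower in 9, higher in 3 and not past in 4 (adjusted p = 0.000104, adjusted p = 0.279 with an estimated correlation), with Nmb (exons shared with Sec11a) at −4.19 and Pcsk1n at −1.11. In the list of growth factors and cytokines 5 of 14 genes were lower, such as the secreted factor gene Bdnf (−4.02), Fgf13 (−1.54), whose product is intracellular, and Cd47 (−0.71), which encodes a membrane protein, and 0 were higher (adjusted p = 0.0284, adjusted p = 0.279 with an estimated correlation). Immediate early and heat shock genes were lower in 5 and higher in 1 of 16, with Jun at −3.09, Junb at −1.60 and Hsp90aa1 at −0.54 (adjusted p = 0.0162, adjusted p = 0.353 with an estimated correlation). Axon injury genes were lower in 3 of 6, Gap43, Flrt3 (−2.10) and Sox11 (−0.93) (adjusted p = 0.00248, adjusted p = 0.279 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 17, lower in 0 and not past in 62 of 79, with Cox8a at 0.64, Atp5j at 0.78 and Uqcr10 at 0.86 (adjusted p = 1.64e-06, adjusted p = 0.279 with an estimated correlation). Ribosomal protein genes were higher in 8, such as Rps9 (0.68), Rps28 (0.44) and Rpl35a (0.44), and lower in 1 of 96 (adjusted p = 0.00248, adjusted p = 0.370 with an estimated correlation). With thinned cells 7 oxidative phosphorylation genes and 1 ribosomal gene passed, all higher, and 7 neuropeptide, 3 immediate early, 2 growth factor list and 1 axon injury genes passed, all lower. Adjusted over the list alone, 11 itch receptor, 13 neuropeptide, 5 growth factor list, 7 immediate early, 4 axon injury, 23 oxidative phosphorylation and 1 ribosomal genes passed.

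Other lists did not pass with camera. Fry called neurotrophic receptors (downward, adjusted p = 0.00905), inhibitory receptors (downward, adjusted p = 0.00472) and the calcium channels above (upward, adjusted p = 0.00472). Ret was higher by 1.12 (SE 0.09) while 4 of 9 neurotrophic receptors were lower, such as Gfra1 (−4.17). Inhibitory receptors were lower in 4 of 10, such as Npy2r (−4.53; listed at 0 in NP1-like cells too) and Grm7 (−2.90), with Cnr1 listed at 0 in TH-like cells against 30.2 CPM (SD 10.8), and higher in 2. Cytokine receptors gave 3 higher, such as Ifngr2 (1.70), and 3 lower, such as Il6st (−1.73) and Lifr (−0.81), of 14. Glutamate and GABA receptors gave 3 higher, and 3 lower, such as Gria4 (−2.47), of 15. Transcription factors gave 5 higher, such as Pou4f1 (1.60) and Runx1 (0.46), and 2 lower, Etv1 and Zeb2 (−3.78), of 14. Of 10 other glial genes, Pmp22 was higher (1.62) and Cd9 (−1.30) and Mal (−2.17) lower, and Schwann cell markers summed to 1235 CPM in TH-like cells against 233 in NP1-like cells. The only innate receptor tested did not pass. With p adjusted over the list alone, 5 neurotrophic, 7 inhibitory, 9 cytokine, 7 glutamate and GABA and 1 innate receptor genes, 8 transcription factors and 3 glial genes passed.

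For TH-like against other neurons as a whole, 1444 of 9016 genes passed in the limma test, 706 higher and 738 lower in TH-like cells, and 1412 moved the same way in all 4 mice. Camera called 10 of 17 lists, 0 with an estimated correlation, and fry called 9. Calcium channels and glutamate and GABA receptors had a negative median beside an upward test, and transcription factors and other glial genes a negative mean. TH-like cells numbered 18 in Blue, 18 in Red, 4 in Control and 3 in Control6, and the count was 860 without Blue, 926 without Red, 2817 in the 2 mice of run 1, 473 in those of runs 2 to 4 and 739 with thinned cells.

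**Figure D4:**
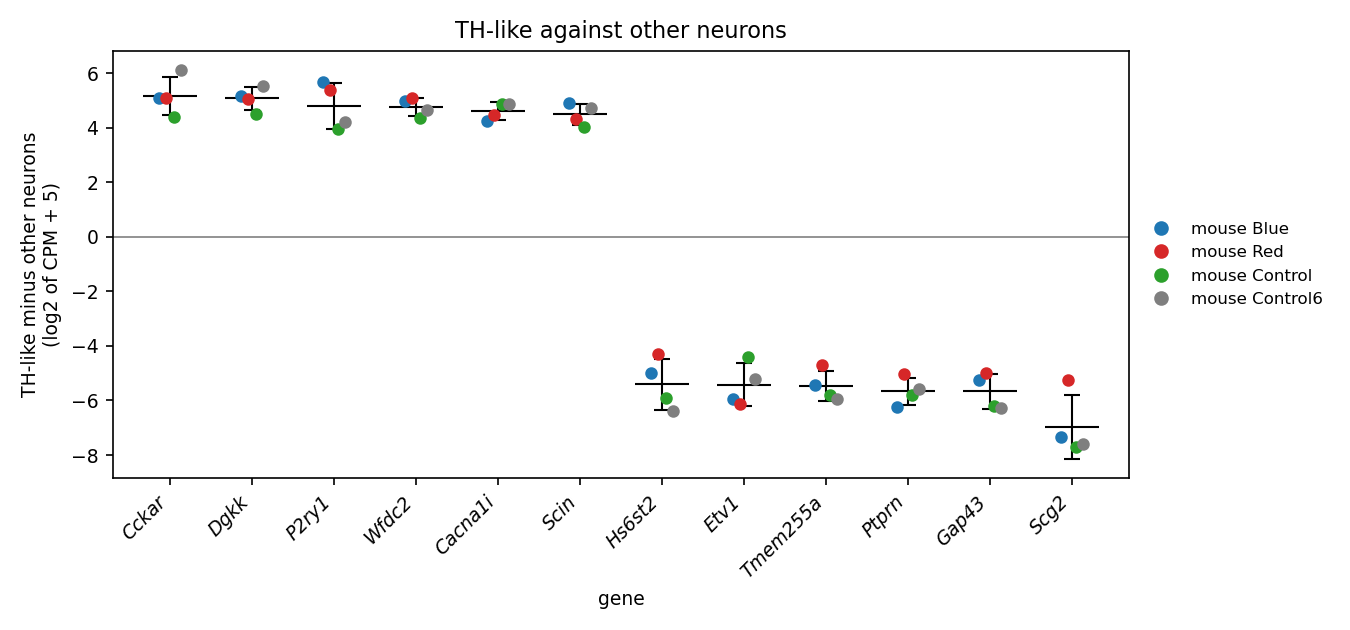
Log2 difference of CPM + 5 between TH-like and other named neurons (y axis) for the 6 largest named genes each way, in 4 mice (points), with the mean and SD (bars). Scg2 shows the largest mean difference, −6.97, and Etv1 was listed at 0 in every TH-like mean.

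NP1-like neurons were compared with NP2-like and NP3-like neurons together in all 6 mice, to ask what separates the Mrgprd-type class from the itch-associated classes. Grik1 stood at 1406 CPM (SD 156) against 20.9 (SD 20.49), a log2 difference of 6.24 (SE 0.33, adjusted p = 3.94e-09). Kcnab1, an auxiliary potassium channel subunit gene, differed by 5.98 (SE 0.28), the protein kinase C gene Prkcq by 5.62, the phosphatase gene Ppm1j by 5.08, Ccdc141 by 4.75 and the vesicle protein gene Rph3a by 4.68. On the other side, Ptprn, a dense-core vesicle protein gene (chromosome 1, 75247027 to 75264502), was listed at 0 in NP1-like cells of all 6 mice, against 679 CPM (SD 97.7) in NP2-like and NP3-like cells (adjusted p = 8.09e-12). Npy2r, a neuropeptide Y receptor gene, and Resp18 were also listed at 0 in NP1-like cells, against 430.5 CPM (SD 188) and 297 CPM (SD 77.8). For Npy2r the NP3-like cells made the difference, at 673 CPM (SD 201, n = 5 mice), as NP2-like cells held only 0.80 CPM (SD 1.13, n = 2 mice). Etv1 was lower by −6.99 (SE 0.23), Hpcal1 by −6.59 and Scg2 by −5.73 (SE 0.13, adjusted p = 1.18e-13).

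Piezo2 was higher in NP1-like cells, at 856 CPM (SD 180) against 123.4 (SD 55.04), by 2.82 (SE 0.19), with Trpa1 at 2.31 (SE 0.43) and P2rx3 at 1.51 (SE 0.14). Trpv1 was lower by −3.04 (SE 0.35), as was Ngfr (−4.29; 312 CPM in NP2-like but 10.5 in NP3-like cells), while Ret was higher by 1.24 (SE 0.10). Potassium and HCN channel genes moved up as a list, 18 higher, 1 lower and 15 not past of 34 (camera adjusted p = 1.28e-06, adjusted p = 0.130 with an estimated correlation), with Kcnma1 at 3.88 and Kcnip4 at 1.67. Itch and inflammatory mediator receptors moved down, 7 lower, 3 higher and 4 not past of 14 (adjusted p = 0.00352, adjusted p = 0.341 with an estimated correlation). The leukotriene receptor gene Cysltr2 was lower by −3.85, S1pr1 was listed at 0 in NP1-like cells against 103.01 CPM (SD 58.5), and Agtr1a was higher by 3.92. NP2-like cells were low in Cysltr2 and S1pr1 as well, at 3.20 and 8.05 CPM, against 161 and 135 in NP3-like cells. Ribosomal protein genes moved down, 23 lower, 2 higher and 71 not past of 96 (adjusted p = 1.93e-07, adjusted p = 0.130 with an estimated correlation), with Rpl9 at −0.43. Among these, Rps27 and Rps27rt are uncertain, as 72.5% and 75.7% of their low values were fractions. With thinned cells 6 ribosomal genes passed, 5 of them lower, and with edgeR on recovered counts 41 of 87 (38 lower, TMM) and 44 of 87 (41 lower, DESeq2 size factors). The potassium and HCN list gave 12 past with thinned cells, all higher. Adjusted over the list alone, 22 potassium and HCN channel, 12 itch receptor and 30 ribosomal genes passed. Satellite glial markers summed to a median of 147 CPM in NP1-like, 270 in NP2-like and 215 in NP3-like cells.

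The remaining lists did not pass with camera. Sodium channel genes gave 2 higher, Scn11a by 0.70 (SE 0.10) and Scn10a by 0.50 (SE 0.11), and 3 lower, such as Scn3b (−1.96) and Scn2b (−3.22), of 8, with a list median of −0.37 that turned to 0.21 with thinned cells, and Scn9a differed by 0.17 (SE 0.09, adjusted p = 0.252) with a sign that turned under other clusterings. Of 18 TRP, Piezo, ASIC and P2X genes 4 were higher and 3 lower, and of 10 calcium channel genes 3 were higher, such as Cacnb4 (4.54), and 3 lower, such as Cacna2d2 (−3.27) and Cacna1c (−0.87). Inhibitory receptors gave 4 higher, such as Adora1 (3.75), and 2 lower, Npy2r and Htr1a (listed at 0 against 96.03 CPM, SD 50.3), of 7; Htr1a was listed at 0 in NP2-like cells too, against 132.3 CPM in NP3-like cells. Glutamate and GABA receptors gave 5 higher, such as Gria1 (3.30), and 2 lower of 11. Neuropeptide genes gave 5 higher, such as Scg3 (1.44) and Cpe (1.25), and 3 lower of 15. Neurotrophic receptors gave 2 higher and 3 lower of 7. The growth factor and cytokine list gave 2 higher, such as Fam19a3 (25.3 CPM, SD 11.1, against a listed 0), and 3 lower, such as Fgf1 (−2.70) and the membrane protein gene Cd47 (−0.63), of 10. Cytokine receptors gave Lifr (0.76) and Il6st (0.79) higher and Il13ra1 (−1.88) lower of 14, and the only innate receptor tested did not pass. With p adjusted over the list alone, 6 sodium, 9 TRP, Piezo, ASIC and P2X and 6 calcium channel genes, 6 inhibitory, 7 glutamate and GABA, 5 neurotrophic, 4 cytokine and 0 innate receptor genes, 10 neuropeptide genes and 5 of the growth factor list passed.

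Transcription factors gave 5 higher, such as Casz1 (2.06) and Runx1 (1.62), and 2 lower of 13. Ier3 was higher (1.63) and 4 of 15 immediate early and heat shock genes lower, such as Egr1 (−2.30) and Jun (−1.58). Axon injury genes gave Sox11 (2.79) and Flrt3 (2.04) higher and 2 lower, such as Gap43 (−4.23), of 5. Oxidative phosphorylation genes gave 3 past of 79, Ndufb8 (0.53) and Ndufa3 (0.51) higher and Cox5a (−0.97) lower, although edgeR on recovered counts gave 14 of 75 (11 higher, TMM) and 10 of 75 (7 higher, DESeq2 size factors), and other glial genes Pmp22 (0.89) higher and Sparc (−2.62) and Gpm6b (−2.12) lower of 8. Adjusted over the list alone, 8 transcription factors, 7 immediate early, 4 axon injury, 1 oxidative phosphorylation and 6 glial genes passed. For NP1-like against NP2-like and NP3-like neurons as a whole, 1459 of 8641 genes passed in the limma test, 801 higher and 658 lower in NP1-like cells, and 1253 moved the same way in all 6 mice. Camera called 3 of 17 lists, 0 with an estimated correlation and 10 with fry, axon injury genes had a positive median beside a downward test, and inhibitory receptors a negative mean beside an upward test. The count was 723 with thinned cells, 936 with at least 10 counts per sum and 949 in the 4 mice of runs 2 to 4, against 2143 in the 2 mice of run 1.

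**Figure D5:**
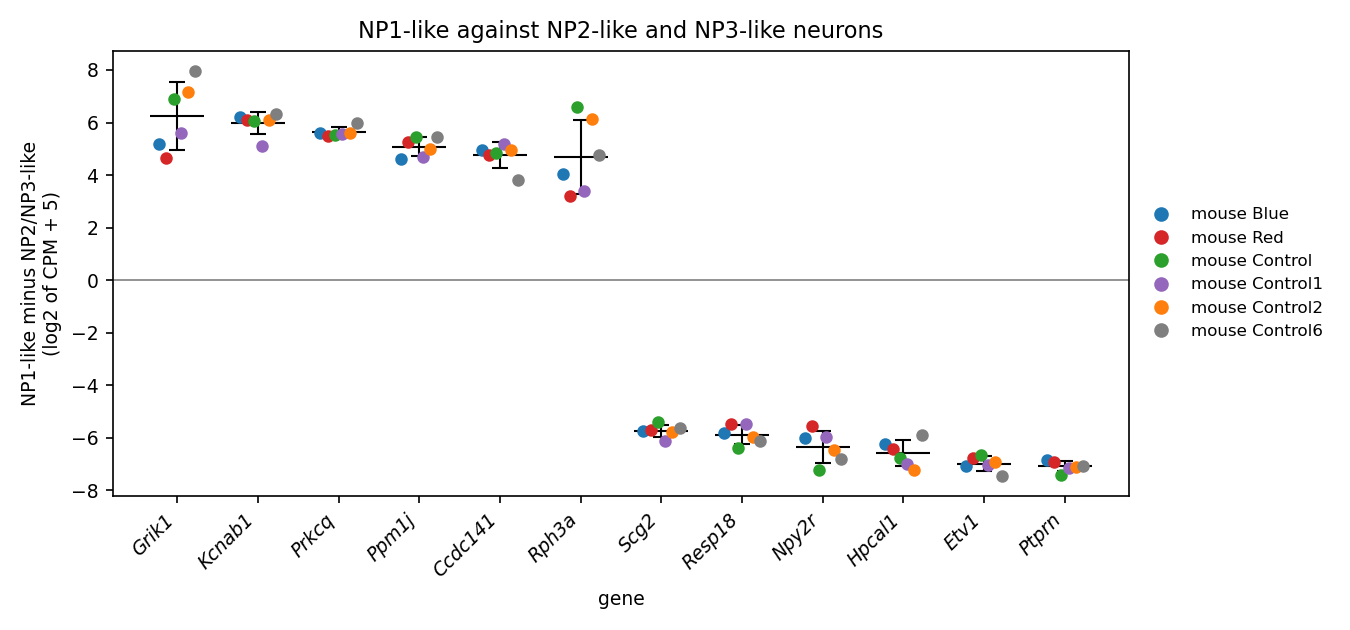
Log2 difference of CPM + 5 between NP1-like and NP2-like plus NP3-like neurons (y axis) for the 6 largest named genes each way, in 6 mice (points), with the mean and SD (bars). Grik1 has the largest mean on the NP1-like side, 6.24, and Ptprn, Npy2r and Resp18 were listed at 0 in every NP1-like mean.

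The opioid receptor gene Oprm1, named in advance, was below the filter of 10 CPM in all 3 comparisons and was not tested. Over all kept cells it averaged 8.18 CPM, with a count in 53 of 371 cells (14.3%, 95% interval 10.9% to 18.3%). It had a count in 14 of 57 PEP1-like cells (24.6%, 95% interval 14.1% to 37.8%), in 10 of 23 PEP2-like cells (43.5%, 95% interval 23.2% to 65.5%), in 10 of 47 NP3-like cells (21.3%, 95% interval 10.7% to 35.7%), in 7 of 48 NP2-like cells (14.6%, 95% interval 6.07% to 27.8%), in 4 of 86 NP1-like cells (4.65%, 95% interval 1.28% to 11.5%) and in 0 of 47 TH-like cells. Median depths of these classes were 20160, 80290, 18580, 41160, 49130 and 31130 counts. The mean over mice was 23.1 CPM in PEP2-like (SD 24, n = 2 mice), 20.8 in NP3-like (SD 28.7, n = 5) and 7.49 in PEP1-like cells (SD 8.69, n = 4).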

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

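Of 203 groups of 4 to 6 mice searched for a mouse far from the others, 16 had one, and chance alone flags about 1 in 20 groups. The tests of shallow sampling, of depth and run for the class shares, and of glial RNA against the nearest class in the same mouse were chosen after the results they concern were seen. No biological explanation was tested for any pattern below, since the labels give 1 condition.

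Several values set a mouse apart in composition or depth. Cells of the 2 clusters left unnamed for their glial genes made up 39.1% of mouse Control2, against 5.26% to 16.4% in the other 5 mice, and the low-count cluster made up 18% of mouse Control, against 0 in the others. Mouse Control also had the highest median depth (47994 counts against 26814 to 33429) and the highest mean Scn10a level over all kept cells (1286.5 CPM against 625 to 784). Control6 stood out with 249.5 CPM of Scn10a in TH-like cells, against 239.0 to 240.7 in the other 3 mice, and with 50.5 CPM of the Y-linked gene Ddx3y, against 0 to 7.87.

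Single genes of a class comparison also stood apart in a mouse. For NP-like against PEP-like neurons, Atp5h was at −1.43 on the log2 scale in Control1, with the other 4 mice from −0.52 to −0.23. For TH-like neurons, Red had the smallest differences for Scg2, −5.23 against −7.69 to −7.35, and for Ptgir, −3.01 against −4.08 to −3.93. For NP1-like neurons, Control1 stood apart for Kcnab1 (5.12 against 6.05 to 6.33), P2rx3 (2.35 against 1.12 to 1.498) and Jun (−4.09 against −1.77 to −0.57). Control6 did for Prkcq (6.00 against 5.50 to 5.59), Ccdc141 (3.80 against 4.75 to 5.19) and Ndufb8 (1.42 against 0.14 to 0.57). Control2 did for Cd47 (−0.073 against −0.84 to −0.67). Each kept its direction in every mouse.

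Data outside the class comparisons also held signal. Of the 63 unnamed cells, 60 (95.2%, 95% interval 86.7% to 99.01%) had an Scn10a count. Entries whose symbols had been turned into dates held 0.154% of the signal in 26 entries and were assigned to no gene.

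The high Scn10a mean of mouse Control came from its 9 low-count cells, which averaged 4277 CPM (SE 911), against 630 CPM (SE 63.9) in its other 41 kept cells. Shallow sampling of ordinary cells was argued against, since named cells of the same mouse thinned to 2319 counts reached at most 1077 CPM (SE 245, 10 NP1-like cells). Loss of cytoplasm, leaving mostly nuclear RNA, may explain the pattern: ribosomal protein genes took 0.301 of their share in the other cells, and 6 of 6 nuclear RNAs were at least 2 times higher, such as Malat1 (14.4 times) and Meg3 (8.32 times), although Neat1 had a count in 1 cell only. Scn9a (5.50 times) and Scn11a (2.92 times) were higher too, and Snap25 was at 0.0748 times; Xist and Snap25 had been seen before this test.

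In 2 clusters whose neuronal markers resembled PEP1-like and NP1-like cells, the 10 strongest genes held more glial genes than markers of those classes, although the larger had only 1 glial gene among them and began with Calb1 and Smr2. RNA of glial cells attached to or caught with neurons stays open. Of 12 glial genes not used to cluster, 66.7% were higher than in the nearest class in the larger cluster and 91.7% in the smaller. A share of 80% in both had been required. Cdh19 and Cryab, 2 of the 12, were among the 3 glial genes that left the smaller cluster unnamed, so its share is not independent of that rule. Free glial RNA spread evenly over the cells of a mouse was not decided by the summed levels of the 12 genes, 1.24 to 1.66 times those of all named cells. Cd9, the highest of the 12, was level with the nearest class (1605 against 1728 CPM in the larger cluster, 975 against 1011 in the smaller). The sum could therefore hardly tell. Summed over 7 members with low levels in named cells, the ratio ran from 1.58 in Control to 2.74 in Control6. Set against the nearest class of the same mouse, the median log2 difference of the 12 was at least 1.41 in 5 of 5 comparisons (mean 1.89, SD 0.50). For the larger cluster (1.41 in Blue and 2.07 in Red) this argues against an even spread. The smaller had been left unnamed partly on Cdh19 and Cryab.

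Class shares differed between mice. A difference in depth between mice was argued against as the whole cause, since with cells thinned to equal depth the permutation p was 1.0e-05, the smallest possible. A difference between runs cannot be told apart from one between mice: the 2 mice of run 3 gave a permutation p of 0.0584 and those of run 1 0.856, while centring markers within runs left 0.00016.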

How the results depend on the processing

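Pseudocounts, Rn45s in the totals, median-of-ratios scaling, joining the 2 clusters with glial genes and PEP1-like cells alone were chosen after the data were seen. EdgeR with TMM was the test first foreseen, and its use on recovered counts as an alternative was set after the data were seen. Of 135 values of the main results under alternatives, 19 moved, 7 no longer passed and 1 newly passed, and the rest kept direction and side of the threshold (counts within 1.5 times). Of 4766 values of named genes 4459 did, 272 no longer passed, 31 newly passed and 4 reversed. Named genes called under every alternative in which they were tested were 36 of 61, 42 of 61 and 43 of 61 for NP-like, TH-like and NP1-like neurons. Some alternatives did not test every named gene. The class shares per mouse, over all mice or all but 1, differed with p that stayed under 0.05 under other settings, from 1e-05 (the smallest possible) to 0.0479 at resolution 0.5, and 0.0162 without Control. Of 153 values of lists, 120 stayed, 19 no longer passed and 13 newly passed.

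For NP-like against PEP-like neurons the count of 1157 became 738 with no filter on low values, 732 with at least 10 counts in every sum, 653 with thinned cells, 2013 in the mice of run 1, 462 in runs 2 to 4 and 746 with PEP1-like cells alone, and 767 to 1323 when each mouse was left out, lowest without Blue. Fry called 4 lists. Npy2r, NP-like against PEP-like neurons, reversed to −0.75 with the mean over cells of log2(CPM + 1). Scn10a differed by 0.70 with cells of at least 2000 genes, where 6 mice allowed an exact p of 0.0313. For TH-like against other neurons the count of 1444 became 739 with thinned cells, 2817 in run 1, 473 in runs 2 to 4, and 860 to 1393 when each mouse was left out (860 without Blue, 926 without Red). Camera with an estimated correlation called 0 lists. At least 5 cells per class left 2 mice, and no value was computed. For NP1-like against NP2-like and NP3-like neurons the count of 1459 became 936 with at least 10 counts in every sum, 723 with thinned cells, 949 in runs 2 to 4, and 1150 to 1355 when each mouse was left out. Camera with an estimated correlation called 0 lists and fry 10. Scn10a differed by 0.42 to 0.55 when each mouse was left out (5 mice allow no exact p under 0.0625) and by 0.38 with thinned cells (exact p = 0.0625). Scn9a, NP1-like against NP2-like and NP3-like neurons, not past the threshold, reversed to −0.023 with clusters on variable genes, −0.19 at resolution 0.5 and −0.17 by the highest marker score. Inhibitory receptors reversed with fry (downward, adjusted p = 0.0335). Fewer mice or fewer counts entered the subsets of mice and thinned cells, yet the mice of run 1 alone gave more genes than all mice. The cause of these changes was not tested.

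Without the mouse block 1162 genes passed for NP-like against PEP-like neurons, 1467 for TH-like against other neurons and 1374 for NP1-like against NP2-like and NP3-like neurons, and 0, 8 and 3 lists. The median of all genes moved to −0.12 (TH-like) and 0.13 (NP1-like) with thinned cells, and to 0.48 for NP1-like cells with the mean over cells of log2(CPM + 1), where 76.95% of calls were higher. Alternatives for NF-like neurons were not run. In simulated sums per mouse and class, which were not means over cells, 2-fold changes were found for 22.7% to 34.4% of genes.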

Other observations

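Among the fixed readout genes, several were highest in the same class in every mouse that had it; these genes were picked after their values were seen, and no test was made. NP3-like cells were highest for the leukotriene receptor gene Cysltr2, at 161 CPM (SD 35.8, 5 of 5 mice), and for the neuropeptide Y receptor gene Npy2r, at 673 CPM (SD 201). PEP1-like cells were highest for Adcyap1, at 1387 CPM (SD 442, 4 of 4 mice), for Gal, at 221 CPM (SD 82.1), and for the artemin co-receptor gene Gfra3, at 181 CPM (SD 48.1). TH-like cells were highest for the T-type calcium channel gene Cacna1i, at 127.8 CPM (SD 36.4, 4 of 4 mice), for P2ry1, at 526 CPM (SD 69), and for the potassium channel gene Kcnd3, at 681 CPM (SD 39.3). NP1-like cells were highest for the angiotensin receptor gene Agtr1a, at 143 CPM (SD 41.2, 6 of 6 mice), and NP2-like cells for the GDNF receptor gene Gfra1, at 480 CPM (SD 38.8, 2 of 2 mice). PEP2-like cells were highest for the sodium channel gene Scn8a, at 264 CPM (SD 59.3, 2 of 2 mice), with 119.9 CPM in TH-like cells.

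Single markers of cold and large-diameter neurons went different ways. Trpm8 had a count in 19 of 371 kept cells (5.12%, 95% interval 3.11% to 7.88%) and Pvalb in 3 (0.809%, 95% interval 0.167% to 2.34%), whereas Nefh had a count in 296 (79.8%, 95% interval 75.3% to 83.8%). The labels give no sex. Xist was listed at 0 in mouse Control6 and averaged 105.6 to 435.8 CPM in the other 5 mice, the highest in Control, where 9 low-count cells held 1804.5 CPM and the other 41 held 135.4.

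The counts of genes past the threshold were set against other splits of the same class means, all tests chosen after the results were seen. For NP-like against PEP-like neurons, 1 of 100 splits drawn gave as many genes, the real one (1157); the highest other gave 9.08% of that number, with 6 of 10 class means in their true place. For TH-like neurons, 1 of 32 usable splits did (1444, highest other 0), and for NP1-like neurons 1 of 98 (1459). The highest other there, 502, had 10 of 12 class means in place. These splits ignore that class means are paired by mouse. Swapping the classes within mice keeps the pairs, and gave 0 genes in every other swap; the 16 and 8 swaps of the first 2 comparisons are too few for a share under 0.05. For NP1-like neurons 1 of 32 swaps gave as many genes. The classes were themselves defined on the same cells, so the real labels were expected to give more genes than other splits, and these counts exclude chance for none of the comparisons.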
